A study of Arabidopsis thaliana with 22 samples.

How the data were processed

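Gene expression was measured in mature leaves of Arabidopsis thaliana Columbia-0 with 22 one-colour oligonucleotide arrays, each hybridised with biotin-labelled cRNA from 1 leaf sample. Per the labels' protocols, RNA was purified on silica columns and amplified by in vitro transcription from double-stranded cDNA. The deposited values were on the log2 scale and had been made with RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set. Its version, the software and the arrays that entered it were not given in the sources used here. The array medians ran from 6.45 to 6.90 and the lowest correlation between arrays was 0.852, and no 2 columns were identical. Forcing the distributions to be alike can hide or invert small changes when many transcripts move in one direction, so other scalings were tried. Arrays have no read depth, and their number limits the precision.

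Samples were grouped by their titles into 6 groups and 3 comparisons. Leaves kept at 37 °C for 1 h were compared with leaves kept at 20 °C (3 and 3 arrays). Leaves infiltrated with azetidine-2-carboxylate (AZC) were compared with leaves infiltrated with L-proline (3 and 3 arrays), and leaves infiltrated with tunicamycin with leaves given its solvent DMF (5 and 5 arrays). On all 6 AZC and proline arrays the title names one compound while the source name and the description name the other. The titles were used, and every sign in that comparison is the group titled AZC minus the group titled proline, which turns if the titles are wrong. The DMF arrays also carry 2 different concentrations in their labels, and the 2 ul/ml of the treatment protocol is given here. The labels describe the replicates as biological.

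The table held 22810 probe sets, of which 64 control probe sets were set aside and 22746 were tested. In the platform annotation given, 13513 of the tested probe sets had 1 gene, 503 had several and 8730 were not named here. Of the named ones, 13436 matched the TAIR10.1 gene table and 77 kept the older name. Genes without a symbol are given by locus tag. Each comparison was fitted on its own arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided. Benjamini-Hochberg adjustment ran over all tested probe sets and the threshold was an adjusted p of 0.05. Errors of log2 changes are standard errors from that fit. Differences between comparisons came from 1 fit over all 22 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

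Before the data were examined, 20 gene lists with 330 loci were fixed, of which 62 loci were measured by a named probe set. They covered cytosolic and nuclear heat shock proteins, organelle and peroxisome chaperones, heat shock factors, chaperone partners, the unfolded protein response of the endoplasmic reticulum (ER), proteasome subunits, ribosomal proteins, photosynthesis, proline metabolism and autophagy. The others covered jasmonate, salicylate, oxidative stress, abscisic acid, the circadian clock, senescence, guard cells, phloem, epidermis and common reference genes. The 7 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. A further 11 lists were written after an exploratory fit had been seen and form a family of their own. Where a locus had several probe sets, 1 was used.

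The genes named in each comparison were chosen by a rule fixed in advance. They are the 10 named probe sets with the largest rise and the 10 with the largest fall among those past the threshold with no overlap between groups, or the 3 with the smallest p in each direction where none passed. Up to 4 members per fixed list were added, and 11 stress genes were to be named always, of which 1, BZIP60, had a named probe set. Only part of these are printed. Between comparisons the rule took the 5 largest differences each way. Genes named outside the rule were chosen after their values were seen, and these are the further list members named beside group counts and the members of the later lists.

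Titles give the same replicate numbers in both groups of a comparison. Deviations from the group means correlated at 0.42, 0.19 and 0.60 for same-numbered heat and control arrays, and at 0.42, 0.82, 0.67, 0.50 and 0.17 for tunicamycin and DMF arrays. All lay above 0.1, so these numbers were taken to pair the arrays, as a pattern of the data and not a statement of the labels. The main fits, list tests and exact permutation tests did not use these pairs. The replicate block was run only as an alternative. In the tunicamycin comparison replicates 3 and 5 correlated as well or better with a DMF array of another number (0.69 and 0.61). For AZC and proline the correlations were 0.35, -0.15 and 0.59, and the numbers were not taken as pairs.

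Alternatives fixed in advance were a fit over all arrays, the replicate number as a block, quantile normalization, median centring, leaving out the dimmest 40% of probe sets, array weights, a variance trend, leaving out cross-hybridizing probe sets, a 2-fold minimum, leaving out each array, and turning the AZC sign. Leaving out both arrays of a replicate number was planned for the correlations of changes and added for the other results after the tunicamycin values had been seen. The fits were tested on simulated data made from the spread of each comparison, with 50 probe sets changed at each of 4 sizes among 22746. For heat, 30%, 78%, 92% and 96% were recovered at log2 changes of 1, 2, 3 and 4. For AZC the shares were 20%, 68%, 82% and 88%, and for tunicamycin 56%, 84%, 98% and 98%. The simulated noise was independent between arrays and between probe sets. It lacked the replicate structure and the correlation between genes of the real arrays, so these shares may not hold for them. The runs also gave 10, 4 and 7 false calls, and a list with no planted change had a camera p of 0.385, 0.588 and 0.0318.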

Results

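Arabidopsis leaves were given 3 treatments known to disturb protein folding, and the transcripts present shortly afterwards were measured on 22 arrays, while misfolded protein itself was not measured in the data used here. The series asks how plants respond to misfolded protein in the cytosol. Heat denatures proteins throughout the cell, AZC is a proline analog that is built into new proteins in place of proline, and tunicamycin blocks N-linked glycosylation and so disturbs folding in the ER. Plants were 5 weeks old. For heat, 6 detached leaves were kept for 1 h at 37 °C or 20 °C, with 3 biological replicates each. AZC or L-proline was infiltrated at 10 mM (3 replicates each) and tunicamycin at 2 mg/l or DMF (5 replicates each), and leaves were taken 3 h later. The mean SD of a probe set within a group, in log2 units, was 0.284 at 20 °C, 0.292 at 37 °C, 0.255 for titled proline, 0.409 for titled AZC, 0.317 for DMF and 0.379 for tunicamycin.

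At 37 °C small heat shock proteins and their partners were among the named genes that rose most. AT1G53540, a cytosolic small heat shock protein, rose by 9.31 ± 0.43 (log2, SE, n = 3 and 3, adjusted p = 0.00012), from 5.49 ± 0.91 to 14.80 ± 0.08 (SD). AT1G52560, an organelle small heat shock protein, rose by 9.22 ± 0.26, ATHSP22.0 of the ER by 8.86 ± 0.18, and Hop3, a co-chaperone that links HSP70 and HSP90, by 8.81 ± 0.36. AT5G51440, a mitochondrial small heat shock protein, rose by 8.35 ± 0.32, the J-domain protein AT1G71000 by 8.24 ± 0.18, the peroxisomal AT5G37670 by 8.09 ± 0.31 and the FKBP-type isomerase AT5G48570 by 7.29 ± 0.27. AT1G72660 and AT2G29500 rose by 7.20 ± 0.24 and 7.13 ± 0.44.

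The named transcripts that fell most at 37 °C belonged to no tested list. AT1G52000, a jacalin-type lectin, fell by 5.82 ± 0.21 (n = 3 and 3, adjusted p = 5.45e-05) and AT4G28240 fell by 4.92 ± 0.24. IAA29, an auxin response repressor, fell by 4.79 ± 0.16, IRX15-L, a gene of xylan synthesis, fell by 4.36 ± 0.23, and TBL26, of a family that acetylates cell wall polysaccharides, fell by 4.11 ± 0.57. AT4G02360, AT3G50270, AT2G22200, AT1G31550 and AT1G76640 fell by 4.29, 4.28, 4.05, 4.05 and 3.99. In each gene named here the mean of the control leaves was also above that of every infiltrated group. AT2G22200 stood at 9.013 in these controls, 4.965 at 37 °C and 4.747 to 4.931 in the infiltrated groups. The 37 °C mean of AT2G22200, AT1G76640 and TBL26 was not below all infiltrated groups, and that of the others was. Whether heat lowered these transcripts or the controls had raised levels was not tested.

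By list, 5 of 7 measured cytosolic and nuclear heat shock proteins rose at 37 °C, also 5 when adjusted over the list alone, with a median of 2.99. Hsp70-2 rose by 2.99 ± 0.39 and the constitutive HSP70 AT3G09440 by 2.70 ± 0.40, while AT4G21870 stood at -0.24 ± 0.47. All 4 organelle and peroxisome chaperones rose (4 adjusted over the list alone, median 8.61). Of 8 chaperone partners 6 rose, 6 adjusted over the list alone (median 4.28), among them HSA32, needed for lasting heat tolerance, by 6.08 ± 0.14, and SQN, a cyclophilin that works with HSP90, by 3.00 ± 0.34. Of 8 genes of the ER unfolded protein response 4 rose (4 higher and 1 lower adjusted over the list alone, median 1.08): DER1, of the derlin family of ER degradation factors, by 3.62 ± 0.15, the transcription factors BZIP28 and BZIP60 by 2.60 ± 0.55 and 1.48 ± 0.23, and ATERDJ3B, an ER J-protein, by 1.03 ± 0.18. Camera gave adjusted p = 3.57e-05 for heat shock proteins, 5.51e-06 for partners and 0.0139 for the ER list. None of these list calls held with an estimated correlation (adjusted p = 0.106, 0.106 and 0.217), and the ER call was also lost with median centring (adjusted p = 0.061, median 1.3) and without both replicate 2 arrays (adjusted p = 0.112, median 0.83). Over all alternatives the adjusted p ran up to 0.106 for heat shock proteins and for partners and from 0.00135 to 0.217 for the ER list. Fry gave unadjusted p = 4.05e-05, 9.52e-06 and 0.000578 for heat shock proteins, partners and the ER list.

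The other tested lists did not pass at 37 °C. Their medians were -0.09 for proteasome subunits (adjusted p = 0.596), -0.12 for ribosomal proteins (0.596), -0.09 for photosynthesis (0.43) and 0.62 for autophagy (0.154). Of 5 autophagy genes ATG8H alone rose, by 1.48 ± 0.35, also 1 adjusted over the list alone, and that list passed with the replicate block (adjusted p = 0.0229, with 0.0229 to 0.654 over all alternatives). Among lists too short to test, AT5G38710, listed under proline metabolism, fell by 3.15 ± 0.67 as 1 of 3 (2 adjusted over the list alone), and the cold- and drought-linked COR47 rose by 0.96 ± 0.18 as 1 of 2 (1 adjusted over the list alone). None passed among PDF1.2 for jasmonate (-2.63 ± 1.3), WRKY53 for salicylate (-1.35 ± 0.57), STZ and GSTU25 for oxidative stress (-0.12 and 0.18), GI for the clock (0.33), FMA for guard cells (0.06) and SWEET11 for phloem (-0.39), and adjusting over the list alone added none. Of 3 reference genes none passed, and 1, AT2G28390, did when adjusted over the list alone (-0.71 ± 0.19). The heat shock factor, senescence and epidermis lists had 0 members with a named probe set. Their genes may be among the 8730 probe sets that were tested without a name. On the same heat arrays the 25S rRNA control probe set stood at 13.81 ± 0.02 against 12.85 ± 0.23 (SD, n = 3 and 3, two-sided exact permutation p = 0.1, the smallest this design allows).

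In all, limma called 1571 probe sets higher and 2409 lower at 37 °C, of which 891 and 1279 had 1 named gene. In 41.1% of probe sets the 2 groups did not overlap, where chance gives 10%. The replicate block gave 2238 higher and 3646 lower. Median centring moved the median of all changes from 0.07 to 0.29 and the share of calls that were higher from 39.5% to 69.2% (4381 and 1950), and without 20 °C replicate 1, 37 °C replicate 1, 37 °C replicate 2 or 20 °C replicate 3 the calls higher numbered 981, 859, 1025 and 993, and those lower 1269 without 37 °C replicate 1.

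**Figure D1:**
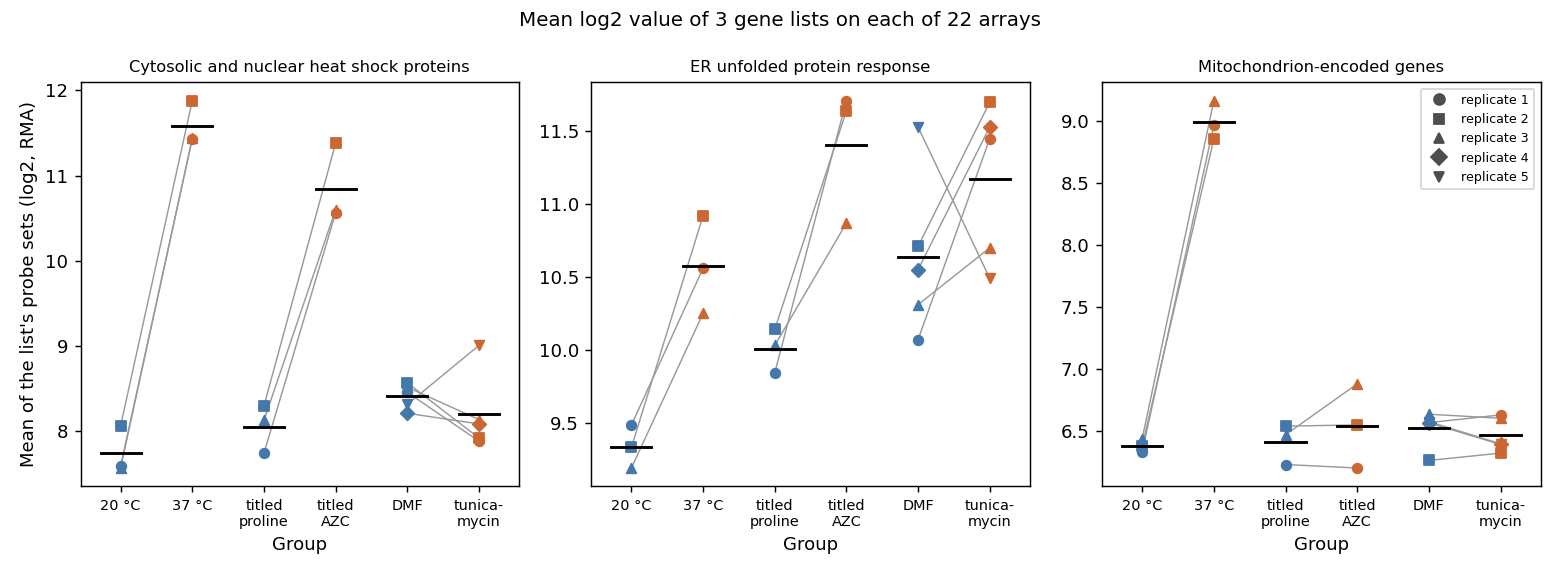
Mean log2 value of the measured members of 3 gene lists on each array, by group, with points for single arrays (marker shape gives the replicate number), grey lines joining same-numbered arrays of a comparison and black bars for group means. Heat shock proteins averaged 11.58 at 37 °C against 7.73 at 20 °C and 10.85 for titled AZC against 8.05 for titled proline, and the ER list ran downward from DMF to tunicamycin in replicate 5 (11.53 to 10.49).

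Several chaperone genes were among the named genes with the largest rise in the group titled AZC over the group titled proline, and the directions in this comparison hold only if the titles are right. AT5G48570 was higher by 5.95 ± 0.65 (log2, SE, n = 3 and 3, adjusted p = 0.0281), AT1G71000 by 5.90 ± 0.47, AT5G51440 by 5.73 ± 0.37, the J-domain protein AT2G20560 by 5.27 ± 0.39 and AT2G29500 by 5.16 ± 0.39. AT1G21550, with calcium-binding motifs, was higher by 5.00 ± 0.36, AT1G53540 by 4.72 ± 0.62, AT1G66080 by 4.49 ± 0.26, the elongation factor subunit AT5G12110 by 4.36 ± 0.26 and the small heat shock protein AT1G54050 by 4.26 ± 0.31. Lower were ARA12, a subtilisin-like protease (-2.31 ± 0.30, adjusted p = 0.0468), AT3G05100 (-1.54), TBL35 (-1.53), the tetraspanin TET7 (-1.49), AT4G26130 (-1.46) and AT5G58090 (-1.11), which were all the named genes that passed in this direction.

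As titled, 3 of 7 heat shock proteins rose in the AZC group, 6 adjusted over the list alone, with a median of 2.78 and all 7 above 0. Hsp70-2 stood at 2.78 ± 0.43 (adjusted p = 0.071). Of 4 organelle and peroxisome chaperones 2 rose, 3 adjusted over the list alone (median 2.16), and AT1G52560 and ATHSP22.0 stood at 0.38 ± 0.14 and 0.61 ± 0.35. Of 8 chaperone partners AT5G48570 and Fes1A, a nucleotide exchange factor of HSP70, rose, 4 adjusted over the list alone (median 1.33), Fes1A by 3.62 ± 0.30. In the ER list DER1 rose by 2.64 ± 0.14 (adjusted p = 0.00359), as 1 of 8, or 4 adjusted over the list alone (median 1.66, all 8 above 0), and BZIP60 and ATERDJ3B stood at 2.18 ± 0.36 and 1.92 ± 0.30. Camera gave adjusted p = 3.6e-09, 0.000247 and 3.66e-07 for heat shock proteins, partners and the ER list, and with an estimated correlation adjusted p = 0.0768 for each. Fry gave unadjusted p = 0.000612, 0.00253 and 0.00149 in the same order.

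No other tested list passed in this comparison. Medians were -0.46 for the proteasome (adjusted p = 0.149), -0.20 for ribosomal proteins (0.303), -0.19 for photosynthesis (0.214) and 0.28 for autophagy (0.564), with 0 members called in each, and 0 adjusted over the list alone. STZ, a zinc finger repressor of stress responses (2.24 ± 0.33), WRKY53 (1.46 ± 0.28) and AT5G38710 (1.61 ± 0.28) passed only when adjusted over the list alone, 1 in each of their lists. PDF1.2, GI, FMA, SWEET11, COR15A and COR47 stood at 0.41, 0.82, -0.25, -0.76, -0.08 and -0.33, and the reference genes had a median of -0.41, with none called, also adjusted over the list alone. The 25S rRNA probe set differed by -0.02 (two-sided exact permutation p = 0.8, n = 3 and 3).

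The comparison gave 102 probe sets higher and 16 lower as titled, 59 and 6 of them with 1 named gene, and 16.1% had no overlap between groups, where chance gives 10%. The counts rested on single arrays: without titled proline replicate 1, 2 or 3 they were 8, 8 and 18 higher and 0 lower each, without titled AZC replicate 1, 2 or 3 they were 1029 and 934, 14 and 0, and 91 and 7. All 102 and 16 had changed by at least 2-fold.

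**Figure D2:**
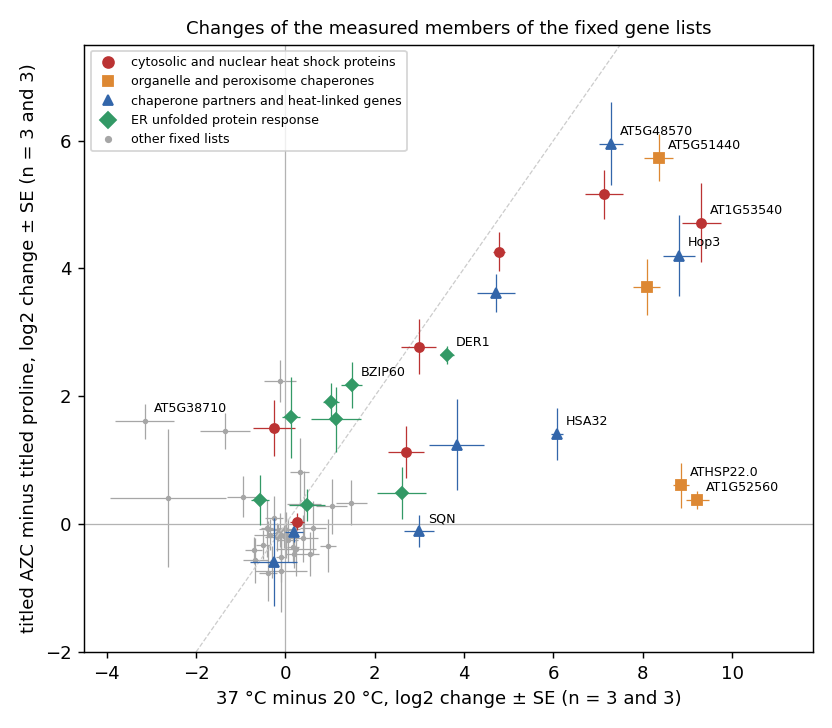
Log2 change at 37 °C against 20 °C (horizontal) and of titled AZC against titled proline (vertical) for the measured members of the fixed lists, with standard errors as bars (n = 3 and 3 in each), colours for 4 lists and the dashed line for equal changes. AT1G52560 and ATHSP22.0 lie at 9.22 and 8.86 on the heat axis and at 0.38 and 0.61 on the other, which turns in sign if the titles are wrong.

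Tunicamycin raised no single gene past the threshold. Of the fixed lists, the genes of the ER unfolded protein response passed as a list at the preset correlation and not with an estimated one. CRT1b, a calreticulin, stood at 0.66 ± 0.62 (log2, SE, n = 5 and 5), the calnexin AT5G07340 at 1.12 ± 0.63, ATERDJ3B at 0.89 ± 0.36, DER1 at 0.84 ± 0.42 and BZIP60 at 0.77 ± 0.49. The median of the 8 members was 0.72, with 6 above 0 and 0 called, also 0 adjusted over the list alone. Camera gave adjusted p = 0.00413 for this list, against adjusted p = 0.575 with an estimated correlation, 0.282 with the replicate block and 0.348 with array weights, and fry gave p = 0.196. The call was also lost without DMF replicate 1, tunicamycin replicate 2 or tunicamycin replicate 4 (adjusted p = 0.452, 0.251 and 0.0792), or without both arrays of replicate 1, 2 or 4 (0.599, 0.118 and 0.104), and over all alternatives the adjusted p ran from 4.47e-11 to 0.886.

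Replicate 5 ran opposite to the others in this list. BZIP60 differed between same-numbered tunicamycin and DMF arrays by 1.36, 1.83, 0.98 and 1.66 in replicates 1 to 4 and by -1.97 in replicate 5. DER1 differed by 1.5, 1.34, 1.75 and 1.32 and then by -1.70. CRT1b was less even, at 2.63, 1.41, -0.79 and 1.26 and then -1.21, and 5 of the 8 members were positive in replicate 3. The list mean differed by 1.38, 0.99, 0.39 and 0.98 and by -1.04 in replicate 5. Over the 5 arrays per group the list means were 11.17 ± 0.54 and 10.63 ± 0.56 (SD, two-sided exact permutation p = 0.167, adjusted p = 0.96 over 20 measures).

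Heat shock genes did not pass with tunicamycin. Medians were -0.16 for heat shock proteins (adjusted p = 0.407), 0.04 for chaperone partners (0.455), 0.13 for the proteasome (0.407), -0.05 for ribosomal proteins (0.935), -0.04 for photosynthesis (0.634) and -0.05 for autophagy (0.634). For partners and ribosomal proteins the camera test pointed the other way from the median, downward and upward. Without tunicamycin replicate 5 the heat shock list was lower (median -0.40, adjusted p = 0.0188), and without tunicamycin replicate 3 the photosynthesis list was higher (median 0.19). AT5G51440 stood at -1.22 ± 0.39 and passed only when adjusted over the list alone, as 1 of 4 organelle and peroxisome chaperones, and in every other list 0 passed when adjusted over the list alone. AT5G38710, PDF1.2, WRKY53, STZ, COR47, GI, FMA and SWEET11 stood at -0.65, -0.51, 0.04, -0.42, 0.30, 0.11, 0.12 and -0.50, and the reference genes had a median of 0.14.

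The genes with the smallest p also missed the threshold in the tunicamycin comparison. AT5G39580, a peroxidase, stood at -3.18 ± 0.63, lower in all 5 tunicamycin arrays than in any DMF array, AT2G47550, a pectin methylesterase, at -1.37 ± 0.29, and AT2G44370 at -1.90 ± 0.45. AT1G04985, AT1G80940 and AT4G30620 stood at 0.43 ± 0.11, 0.36 ± 0.10 and 0.58 ± 0.19. Their adjusted p was 1 in limma. The count was 0 higher and 0 lower, with 310 probe sets at an unadjusted p under 0.05, where 1137 are expected by chance, and 1583 with the replicate block, which also called 0. Without both replicate 5 arrays, an alternative chosen after seeing the data, 24 probe sets were higher and 0 lower, and with the replicate block as well 75 and 59.

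AT5G48570, AT1G71000, AT5G51440, AT2G20560 and AT2G29500 rose with heat and, as titled, with AZC, while other chaperones differed. Of the 102 probe sets higher as titled with AZC, 65 were also higher with heat, where independent lists would share 7.04, and of the 16 lower ones 7 were also lower, where 1.69 would be shared. Without replicate 2 or replicate 3 the AZC comparison itself called 0 probe sets, so no overlap could be counted, and without replicate 1 of both comparisons 57 were higher and 1 lower in both. These comparisons have no control arrays in common. They also differ in time (1 h and 3 h), in handling (detached and infiltrated leaves) and in the type of control. Differences between heat and either infiltrated treatment, here and below, cannot be assigned to the treatment alone. AZC and tunicamycin also had different controls. AT1G52560 and ATHSP22.0 changed more with heat than with AZC, by 8.84 ± 0.25 and 8.25 ± 0.42 (adjusted p = 5.88e-14 and 1.33e-10 in the fit over all 22 arrays). AT5G47610, AT5G07330 and AT1G76880 also changed more with heat, by 7.20, 6.71 and 5.23. In the other direction AT5G12340 differed by -6.58 ± 0.73 (-3.61 with heat and 2.97 with AZC), AT3G53600 by -5.68, AT1G24140 by -5.36, AT3G48450 by -5.32 and AT2G32030 by -5.26. With the AZC sign turned, AT1G71000 and AT5G51440 led instead (14.14 and 14.09), with AT1G52000 and AT4G28240 at the other end (-6.62 and -5.98).

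As lists, the chaperone partners differed between heat and AZC (median difference 1.96, adjusted p = 5.34e-05, and adjusted p = 0.00329 with an estimated correlation). The heat shock proteins and the ER list gave median differences of 0.52 and -0.60 that did not pass (adjusted p = 0.385 and 0.817). The heat shock list stood higher with heat than with tunicamycin (3.70, adjusted p = 7.56e-07, and adjusted p = 0.00149 with an estimated correlation). It also stood higher with AZC than with tunicamycin (3.49, adjusted p = 1.05e-09, and adjusted p = 0.000362 with an estimated correlation). With the AZC sign turned, the latter difference was -2.06 (camera adjusted p = 3.56e-11, and 0.000159 with an estimated correlation). The ER list differed between AZC and tunicamycin by 0.83 (adjusted p = 0.00896, and adjusted p = 0.303 with an estimated correlation), and between heat and tunicamycin by 0.50 (adjusted p = 0.301). With the AZC sign turned, the ER difference between AZC and tunicamycin was -2.55 (camera adjusted p = 2.16e-09, and 0.00819 with an estimated correlation). The tunicamycin side includes replicate 5, where the ER list mean differed by -1.04, against 1.38, 0.99, 0.39 and 0.98 in replicates 1 to 4. These differences were not refitted without both replicate 5 arrays. AT5G51440, AT1G71000, AT5G48570, AT2G20560 and AT2G29500 led the difference between AZC and tunicamycin (6.95, 6.70, 6.69, 5.82 and 5.71), with AT2G29290, AT5G24490, AT5G50420, AT1G17430 and AT3G05100 at the other end (-2.66, -2.50, -2.30, -2.22 and -2). Turning the AZC sign put ARA12 and AT1G14890 at the head of this difference. AT5G48570, AT1G53540 and AT1G71000 then stood at the other end of the difference (-5.214, -5.132 and -5.099). AT5G51440, Hop3, AT1G52560, AT1G71000 and AT1G53540 led that between heat and tunicamycin (9.57, 9.32, 9.17, 9.04 and 8.89).

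In all, 1951 probe sets changed differently with heat and with AZC (816 more positive with heat and 1135 more negative), 2749 with heat and with tunicamycin, and 417 with AZC and with tunicamycin. The last count was 238 without titled proline replicate 1, 193 without titled proline replicate 2, 1368 without titled AZC replicate 1, 165 without titled AZC replicate 2 and 742 without tunicamycin replicate 3. With the AZC sign turned, 3909 and 184 differed in the comparisons that hold AZC, 1 probe set was higher in both heat and AZC, and the heat shock and ER lists differed between heat and AZC by 5.76 and 2.86. Across the 22746 probe sets, which are not independent replicates, log2 changes of heat and AZC correlated at r = 0.316, of heat and tunicamycin at 0.00198 and of AZC and tunicamycin at -0.323. For AZC and tunicamycin, leaving out replicate 2 of every group gave r = -0.196 across the same probe sets. Neither these counts nor these correlations were run without both replicate 5 arrays of the tunicamycin comparison.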

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

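The tests of replicate 5 and of the organelle transcripts were chosen after their values had been seen. Arrays of the tunicamycin and DMF groups were looked at for a single array far from the other 4, by the ratio of its gap to the group's range. Of 68 group and measure pairs, 10 passed the critical value, where chance gives about 3.4, and the measures are not independent. Of these, 7 were on the replicate 5 arrays. Tunicamycin replicate 5 had BZIP60 at 10.56 against 12.46 to 12.93 in the other 4 (ratio 0.802), ATERDJ3B at 11.67 against 13.02 to 13.30 (0.827), DER1 at 10.33 against 11.89 to 12.42 (0.749) and AT4G30620 at 8.37 against 8.99 to 9.14 (0.8). Its heat shock mean was 9.001 against 7.88 to 8.13 (0.774). DMF replicate 5 had DER1 at 12.03 against 10.55 to 10.91 (0.756) and a mean of secretory pathway genes of 10.77 against 10.01 to 10.15 (0.815).

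In replicate 5 the ER and secretory genes stood in the DMF array where the other 4 tunicamycin arrays stood, and the reverse. RNA quality is argued against, as the 3' minus 5' difference of the pair was -0.026, smaller in size than in 3 of the other 4 pairs. A mere lack of response is not decided. For the ER list (-1.04) its error over members (0.305) had excluded a lack of response and its range between pairs (1.3) had not. The secretory list was taken up after these bounds. It differed by -0.719 where the spread of the other 4 pairs (SD 0.0879) gives a 95% range of 0.28 on either side of 0. Of its 16 members 7 were positive and 9 negative in replicate 5, so no conclusion is drawn from it. An exchange of the labels stays open: outside the heat shock, ER and secretory lists the replicate 5 difference correlated at -0.254 with the mean of the other pairs, between the 0 and the bound of r under -0.3 set for the test, while pairs 1 to 4 gave 0.144, 0.471, 0.177 and 0.46 with the mean of the others. Of 16 splits that part all 5 pairs, the one with replicate 5 exchanged called the most, 165 probe sets, but the heat shock mean of tunicamycin replicate 5, 9.001, lies above the 8.20 to 8.56 of DMF replicates 1 to 4 too, so that an exchange alone may not account for it, while a real opposite response in these leaves was not tested and the labels were kept.

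Tunicamycin replicate 3 had the lowest photosynthesis mean, 12.23 against 13.70 to 13.92 (ratio 0.868), and the lowest mean of the wider list of nuclear photosynthesis genes, 12.50 against 13.15 to 13.25 (0.869). DMF replicate 2 had a mean of mitochondrion-encoded genes of 6.26 against 6.57 to 6.64 (0.811). Among the 64 control probe sets, which entered no comparison, a GAPDH probe set at the 5' end was higher at 37 °C in all 3 arrays, at 11.87 against 10.39 to 10.90 (difference of means 1.22), and one at the 3' end was higher too, at 13.39 against 11.73 to 12.55 (1.19).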

How the results depend on the processing

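Leaving out both arrays of a replicate number was chosen after seeing the data, except for the correlations, and unless said otherwise the cause of a change was not tested. Calls higher at 37 °C were 1571, and 4381 with median centring, 1047 with the dimmest 40% left out (fewer probe sets tested), 911 at 2-fold or more and 428 to 1436 with arrays or numbers left out. Calls lower were 2409, and 3646 with the replicate block and 609 to 2321 with arrays or numbers left out. AZC calls higher as titled, 102, became 480 in the fit over all arrays, 263 with median centring, 215 without the dimmest, 3053 with array weights, whose iteration stopped before it converged and gave titled AZC 2 a weight of 6.91, and 179 with the variance trend, with 0 to 1029 over arrays or numbers left out. Calls lower, 16, became 319, 75, 46, 4104 and 26 in the same order, 4 with the replicate block and 0 to 934. The replicate block gave 85 AZC calls higher, and not every array correlated best with its own number. Tunicamycin calls stayed at 0 under every planned setting. With arrays or numbers left out there were 0 to 24 higher, the 24 without replicate 5, and with the replicate block and replicate 5 left out 75 and 59, with replicate 2 left out 1 lower. The ER list kept its direction in every comparison. At 37 °C its median was 1.08, or 1.08 with an estimated correlation and 1.3 with median centring (call lost), and 0.768 to 1.28 with arrays or numbers left out, where the call was lost without replicate 2. With AZC it was 1.66 with an estimated correlation (lost), and 0.877 to 2.23 with arrays or numbers left out. With tunicamycin it was 0.715 with the replicate block, with an estimated correlation and with fry and 0.404 with array weights (all lost), and 0.395 to 1.28 with arrays or numbers left out. Heat shock proteins and partners lost the call with an estimated correlation alone, at 2.99 and 4.28 with heat and 2.78 and 1.33 with AZC. Autophagy at 37 °C passed at 0.62 with the replicate block and without the dimmest. Over arrays or numbers left out it ran from 0.36 to 0.789 and passed without 37 °C replicate 1 (0.789) and without both replicate 1 arrays (0.574), not in the others. With arrays left out, lists that passed in part of the fits ranged from -0.764 to -0.147 (proteasome, AZC), -0.184 to 0.739 (autophagy, AZC), -0.148 to 0.194 (photosynthesis, tunicamycin) and -0.528 to -0.00557 (heat shock proteins, tunicamycin). The wider ribosomal list with tunicamycin, 0.077, turned to -0.0314 with array weights and to -0.0239 without tunicamycin replicate 3, and its test turned without replicate 3 (median 0.00173), over a range of -0.0239 to 0.113. Differences between heat and AZC, 1951, became 4683 with array weights and 3909 with the AZC sign turned; heat and tunicamycin, 2749, became 5507 with array weights; AZC and tunicamycin, 417, became 670 with the replicate block, 6435 with array weights, 184 with the sign turned and 165 to 1368 with arrays left out. Turning the sign gave correlations of -0.316 and 0.323, by construction, and leaving out numbers gave -0.304 to -0.196 for AZC and tunicamycin. Probe sets higher with both heat and AZC, 65, became 187 in the fit over all arrays, 134 with median centring, 105 without the dimmest, 569 with array weights, 1 with the sign turned and 0 to 57 with numbers left out (0 where AZC itself called 0). Those lower with both, 7, became 130, 23, 16 and 1043 in that order, 2 with the replicate block, 4 with quantile normalization and 0 to 1 with numbers left out (0 again where AZC called 0). Of 337 refits of genes named for heat 2 lost the call, and of 272 for AZC 112 did. The replicate block changed no other call of the fixed lists. The pseudocount alternative was not run, as the values were already log2. Leaving out the dimmest 40% bears on signal over background, which limits dim probe sets.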

Other observations

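The gene lists and tests in this part were chosen after the data had been looked at, except the test of the AZC titles, whose outcome was set down beforehand, and the splits of the samples. Transcripts encoded in the mitochondrial genome rose at 37 °C. Of 16 measured, 15 rose, also 15 adjusted over the list alone, with a median of 2.69 (camera adjusted p = 1.99e-12, and adjusted p = 0.0311 with an estimated correlation). Among the largest rises were those of complex I subunits, with nad6 up by 5.55 ± 0.36, nad4L by 4.34 ± 0.17, nad5 by 4.23 ± 0.27 and nad9 by 4.22 ± 0.20 (SE, n = 3 and 3), and cox2 of cytochrome oxidase rose by 4.32 ± 0.16. Their medians were 0.04 with AZC as titled and -0.04 with tunicamycin (adjusted p = 0.285 and 0.106), and the tunicamycin list passed without DMF replicate 2 (-0.07, adjusted p = 0.00606), without tunicamycin replicate 1 (-0.09, 0.0407) and with array weights (-0.14, 0.000599). The 69 plastid-encoded probe sets had a median of -0.03 at 37 °C with 6 lower and 0 higher (adjusted p = 0.425), of -0.08 with AZC and of 0.01 with tunicamycin. The last ones depended on few arrays. With tunicamycin the median was -0.06 without tunicamycin replicate 2 and 0.06 without tunicamycin replicate 1 (adjusted p = 0.000222 and 0.0234). With AZC it was 0.11 without both replicate 2 arrays and -0.18 without both replicate 3 arrays (0.00726 and 0.0208). J proteins and HSP70 and HSP90 partners outside the first lists rose at 37 °C in 5 of 10 (median 2.06, adjusted p = 0.000143, and adjusted p = 0.127 with an estimated correlation), with AT2G20560 up by 6.66 ± 0.35 and BOB1, needed for heat tolerance and development, by 4.16 ± 0.22. With AZC as titled 1 of them, AT2G20560, rose (median 0.93, adjusted p = 0.000748, and adjusted p = 0.18 with an estimated correlation), and with tunicamycin none did (0.03, adjusted p = 0.944).

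Genes of the secretory pathway were looked at in each comparison, without a test of the difference between comparisons. At 37 °C 4 of 16 fell and 1 rose (median -0.59, adjusted p = 0.0594, against 0.0432 with the replicate block, 0.0354 with array weights, 0.0446 with fry, 0.0299 with median centring, but 0.178 with quantile normalization, 0.563 without the dimmest 40% and 0.617 with an estimated correlation), with AT2G01720, a subunit of the oligosaccharyltransferase, at -1.76 ± 0.23 and DER2.1, a derlin, at 1.02 ± 0.21. With AZC as titled 3 rose, AT4G29520 by 2.54 ± 0.30, AT1G29310 of the SEC61 channel by 2.02 ± 0.16 and DER2.1 by 1.80 ± 0.20 (median 0.34, adjusted p = 0.00583, and adjusted p = 0.18 with an estimated correlation), and the list call was lost without titled AZC replicate 1 (adjusted p = 0.218), without both replicate 1 arrays (0.207), in the fit over all arrays (0.143) and with array weights (0.22). The members were mixed in this comparison, with 8 above 0 and 8 below, down to -1.42. Adjusted over the list alone, 8 were higher and 3 lower. With tunicamycin the median was 0.50 with 0 called (adjusted p = 0.000917, and adjusted p = 0.419 with an estimated correlation and 0.0726 with the replicate block), and GPT, the enzyme that tunicamycin inhibits, stood at 0.51 ± 0.29. In the list of ubiquitin-conjugating and U-box enzymes PUB43, PUB24, PUB25, PUB26 and UBC16 fell at 37 °C (-2.29, -1.99, -1.42, -1.34 and -0.74) and UBC31 rose (0.48), while the list did not pass (median 0.03, adjusted p = 0.477). With AZC as titled none of the 21 passed, PUB23, UBC32 and PUB22 stood at 2.53 ± 0.44, 1.62 ± 0.23 and 1.36 ± 0.26, and the median was 0.35 (adjusted p = 0.000748, and adjusted p = 0.161 with an estimated correlation). Over arrays or numbers left out that median ran from 0.134 to 0.509. With tunicamycin it was 0.05 (0.944). The 8 subunits of the chaperonin CCT and prefoldin all stood below 0 with AZC as titled, none called (median -0.88, adjusted p = 0.00408, and adjusted p = 0.473 with an estimated correlation). Between same-numbered arrays, which were not taken as pairs, the list mean differed by 0.06, -1.37 and -1.05 in replicates 1 to 3. Over the 2 groups the two-sided exact permutation p was 0.3. Titled AZC 1 stood at 9.96 against 8.70 and 8.36 for titled AZC 2 and 3. The call was lost without titled AZC replicate 3 (median -0.44, adjusted p = 0.126). The median was 0.20 at 37 °C with AT3G03960 up by 1.2 ± 0.20 and 0.06 with tunicamycin, where the list passed without tunicamycin replicate 3 (median 0.29, adjusted p = 0.0301).

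Of 112 cytosolic ribosomal proteins 94 stood below 0 with AZC as titled (median -0.20, adjusted p = 0.00298, and adjusted p = 0.687 with an estimated correlation) and 86 above 0 with tunicamycin (median 0.08, adjusted p = 0.00869, and adjusted p = 0.805 with an estimated correlation), against a median of -0.09 at 37 °C (0.26). The heat list passed with the replicate block (adjusted p = 0.0449), without 20 °C replicate 2 (median -0.30, 0.00291) and without 37 °C replicate 3 (-0.30, 0.00429), but not with an estimated correlation (adjusted p = 0.935), and its median ran from -0.30 to 0.13 over all alternatives (adjusted p up to 0.999). The tunicamycin direction rested largely on replicate 3, with 101 of 112 positive: the median turned to -0.02 without tunicamycin replicate 3 and to -0.03 with array weights. With AZC the same-numbered arrays of replicate 1, not taken as a pair, had 74 positive. The AZC call was lost without titled proline replicate 2, titled AZC replicate 2 or titled proline replicate 3 (adjusted p = 0.12, 0.0843 and 0.0559). The AZC median ran from -0.339 to -0.0425 with arrays or numbers left out. None was called in either chemical treatment, and 1 rose and 1 fell at 37 °C. Expansins and XTH enzymes of the cell wall had a median of -0.07 with tunicamycin (adjusted p = 0.00251, and adjusted p = 0.644 with an estimated correlation), 0.08 at 37 °C and 0.03 with AZC. The wider photosynthesis list had medians of -0.26, -0.18 and 0.07 with heat, AZC and tunicamycin (0.31 and passing without tunicamycin replicate 3, adjusted p = 0.0492), the glutathione and UDP-sugar transferases of 0.03, -0.09 and 0.01, and 4 further proteasome subunits, too few to test, of 0.14, -0.32 and 0.03. At 37 °C 1 of these 4 subunits fell and 0 rose, with changes from -2.19 to 0.992. Of 61 transferases 3 rose and 6 fell, and of 27 cell wall genes 1 rose and 3 fell. Among all 22746 probe sets 1571 rose and 2409 fell. Median and test pointed different ways for the cell wall list with heat and AZC, the transferases with heat and tunicamycin, the ubiquitin enzymes with heat and tunicamycin, and the plastid-encoded genes with tunicamycin, none of which passed.

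For the mitochondrial transcripts at 37 °C, an offset between whole arrays left in the deposited values was too small to account for the rise. The array median of these values differed by -0.219. They had already been through RMA, so they do not show what an offset before that step or its removal did. The median of the list stayed at 2.75 or more after quantile normalization and median centring. That test could hardly fail, since RMA had already made the distributions alike, so no conclusion is drawn from it. Stronger labelling of transcripts that lack a poly(A) tail stays open. Plastid-encoded probe sets of like signal had a median change of 0.331, under the 0.5 set for the test, but only 4 lay in that range, and the 65 brighter ones had a median of -0.04. The 25S rRNA probe set, also without such a tail, was 0.97 higher, which goes with that explanation. A response of the mitochondria to heat may equally underlie the pattern and was not tested apart from it.

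The arrays titled AZC carry proline in their source names and descriptions, and the reverse. It was set down beforehand that heat shock proteins would be lower in the arrays titled AZC if the titles were wrong, and higher if the other labels were. The median of the list was 2.78 higher in the arrays titled AZC, with all 7 members above 0, which argues against wrong titles and is consistent with wrong source names and descriptions (adjusted p = 0.0768 with an estimated correlation). The reading rests on the assumption that AZC and not proline raises heat shock genes, and the groups were not changed by it.

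Other splits of the same arrays were counted for each result. The 6 heat arrays make 10 splits, too few for a share under 0.05. The real split called 3980 probe sets, as 1 of 10, and the highest of the others 0. For AZC, also with 10 splits, the real one called 118 and the highest other 565, so that 2 of 10 were as large. The larger one set titled proline 1, titled proline 2 and titled AZC 1 against the rest, which points to a structure of the samples apart from the titles. For tunicamycin no split can call fewer than the real count of 0, so nothing could be decided by the 100 splits drawn. The highest, 6430, put both arrays of replicates 1 and 3 with DMF 5, a structure of the samples that follows the replicate numbers. Within pairs, with the replicate block, the real count was also 0, so the outcome of the 16 splits was fixed in advance too. They were also too few for a share under 0.05, and the highest other gave 165. For the differences between comparisons labels were permuted within each, in 100 splits. Between heat and AZC 5 were as large as the real 1951 (highest other 3909), and between heat and tunicamycin 8 were as large as 2749 (highest other 4369), so chance is not excluded by this count. All 5 and 8 kept the true heat labels, and splits without them gave at most 67 and 0. The 3909 equals the count with the AZC sign turned, which keeps every true group. That split is among the 5 but is not a chance arrangement. Between AZC and tunicamycin 4 were as large as 417 (highest other 887). That share is just under 0.05, but the labels were permuted without regard to the tunicamycin pairs and 100 draws do not tell 4 from 5, so chance is not taken as excluded.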
